A study of Homo sapiens with 6 samples.

How the data were processed

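RNA was measured in CaSki, an established human cervical squamous carcinoma cell line that carries human papillomavirus type 16. Per the labels, a culture with a stable lentiviral knockdown of NSUN2, an RNA 5-methylcytosine (m5C) methyltransferase, was set against a control culture whose sample name reads ShNC and whose genotype is given as wild type. The 6 samples fell into 6 groups of 1 library each: RNA sequencing, an m5C library and a mock library of each culture. The part the mock libraries played is not given in the sources used here. Values of 3 samples were analysed here: both RNA-seq libraries and the m5C library of the knockdown. The m5C library of the control and both mock libraries were not analysed here.

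Per the submitters' processing notes, reads were handled with cutadapt 1.9.3 and STAR, whose version was not stated, on the genome build hg19. The read counter, the gene annotation and the methylation caller are not given in the sources used here. Per the file headers, the authors deposited raw counts of reads per protein-coding Ensembl gene for the control and the knockdown RNA-seq library. Beside them the authors deposited a column of normalized counts per library, and its values, below 0 for low counts, behave as log2 CPM (read counts scaled to the library total). For each listed cytosine of the knockdown m5C library the authors deposited the count of covering reads, the count of reads with C and the count of reads with another base than C or T. The authors' deposited methylation level is a fraction, and at every site it equals the reads with C divided by the covering reads with C or T. An adjusted p-value of the methylation call was deposited by the authors and was not used here. In RNA bisulfite sequencing unmethylated cytosine is read as T, so C that remains is counted as methylated, and cytosine that escaped conversion is counted the same way. Before the analysis 1 line of the expression table and 35 lines of the site table had been emptied. No sample column was left unmapped (0 columns).

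The expression table held 13945 rows with 13933 gene symbols, and rows of the 11 symbols on more than 1 row were summed. Counts totalled 26863126 in the control library and 16037794 in the knockdown library. TMM factors from edgeR 4.0.16 in R 4.3.3 were 1.01 for the control and 0.992 for the knockdown, and log2 CPM were computed as in edgeR with a prior count of 1. A gene was called measured at 1 CPM or more in at least 1 library. A gene was called higher or lower at an absolute log2 difference of at least 1. With 1 library per group there was no replicate error, no test between cultures and no p-value. Differences describe 2 libraries, not 2 conditions.

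Fold differences are given with 95% intervals from the exact conditional binomial distribution of 2 Poisson counts, and shares with 95% Wilson intervals. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Where a gene had 0 counts in 1 library, the fold was computed against a floor of 3 counts in that library and given as a bound. This bound leaves out counting error in the other library, so the exact interval allows smaller folds. For each of 42 gene lists written before the data were examined, the median log2 difference over measured members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. Lists with at least 4 measured members were used, which held for 39. A median beyond the 2.5 or 97.5 percentile was counted as standing apart.

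Sites with at least 20 covering reads were used. Regions are as annotated in the deposited table. Sequence context was read from the 21 nt around each site in that table. The contexts CNGGG (the site followed by any base and GGG) and CTCCA, described for NSUN2 and NSUN6 in the literature, were counted. CTCCA was counted with the site at any of its cytosines, so neighbouring sites could share the same motif. No genome of the same build was used here, so the background of all cytosines in these transcripts was not computed. Coordinates are printed as the deposited table gives them. The names and the order of neighbouring genes came from the RefSeq gene table of GRCh38.p14, with no coordinates taken from it.

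The named genes followed a rule written before the data were examined. NSUN2 came first, then the 15 largest increases and the 15 largest decreases among genes at 5 CPM or more in at least 1 library. Up to 4 members with the largest absolute difference were taken from each list, with all RNA m5C methyltransferases and KRT13. KRT13 was fixed by name because the publication on this series is known to be about it. Its place on the list of proposed NSUN2 substrates may therefore not be independent of these data. Sites were the 10 with the highest level at 100 or more reads and those in genes of the list of proposed NSUN2 mRNA substrates. Genes and sites named outside this rule are said to be chosen after their values were seen.

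On simulated counts of 11524 genes for this comparison, 100% of genes changed by 1.5 or 2 on the log2 scale in either direction were recovered by the 2-fold rule. Of 11324 unchanged genes 21 passed it. Among simulated unchanged lists of 20 genes, 4% fell outside the central range of random lists, and 100% of lists shifted by 0.5 were found. The changed genes were drawn at 5 CPM or more, and the simulation held counting error only. The spread between the 2 libraries was 3.62 to 13.4 times counting error, so these rates do not describe separate cultures. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for all other steps. Alternatives planned before the data were examined covered the pseudocount, the scaling of the knockdown library, rows that share a symbol, the expression minimum, the fold threshold, the coverage minimum, the methylation level and sites close to one another. Size factors from DESeq2 1.42.0, library totals without further scaling, the authors' deposited log2 values, the omission of mitochondrial or ribosomal protein genes, and random lists matched on knockdown expression for genes with a site were added after seeing the data.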

Results

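CaSki cells with and without a stable knockdown of NSUN2 were profiled by RNA sequencing, to compare gene expression, and by RNA bisulfite sequencing, to read 5-methylcytosine. The expression data comprised 1 control library of 26863126 counts and 1 knockdown library of 16037794 counts, a ratio of 1.67. Of 13933 gene symbols, 11779 reached 1 CPM in at least 1 library and 281 had no count in either. The methylation data comprised 5955 listed cytosines of the knockdown m5C library. Each group had 1 library, so no difference below has a replicate check.

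NSUN2 (ENSG00000037474), the targeted gene, was measured first as a check of the labels. It had 11115 counts in the control and 1965 counts in the knockdown library, or 410.4 and 124 CPM. Expression was 3.32-fold lower in the knockdown library (95% counting interval 3.17 to 3.49), a log2 difference of -1.73. Among 2619 genes at 100 CPM or more in at least 1 library, NSUN2 had the lowest log2 difference and was the only gene at least 2-fold lower. The other measured RNA m5C methyltransferases stayed within 2-fold. These were NOP2, a ribosomal RNA methyltransferase, with a log2 difference of 0.20, NSUN3 with -0.26, NSUN4 with -0.43, NSUN5 with 0.29, NSUN6 with 0.18 and TRDMT1, the tRNA enzyme DNMT2, with 0.45. All 10 measured m5C readers and oxidases and all 19 measured genes of the m6A machinery also stayed within 2-fold. The differences furthest from 0 among the readers and oxidases were those of TET2, an oxidase of methylcytosine, at -0.85, SRSF2 at -0.69, ALKBH1 at -0.52 and YBX1, a binding protein of m5C in mRNA, at 0.39. Among the m6A genes it was that of WTAP at -0.41.

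The comparison of the transcriptomes gave 520 genes at least 2-fold higher and 499 genes at least 2-fold lower in the knockdown library. IRF3 (ENSG00000126456), a transcription factor of the innate antiviral response, was the only gene at 100 CPM or more that was at least 2-fold higher. Its level was 57.1 CPM in the control and 261 CPM in the knockdown library, 4.57-fold higher (4.31 to 4.85). At the low end, PTGIS, the prostacyclin synthase, had 210 counts in the control and 0 in the knockdown library, at least 41.1-fold lower. PPAP2B, a lipid phosphate phosphatase, was 15.2-fold lower (6.82 to 42.0) and ENPP1, an ectonucleotide pyrophosphatase, 6.97-fold lower (4.04 to 13.0). RRM2B, a p53-inducible subunit of ribonucleotide reductase, was 6.85-fold lower (3.80 to 13.6). DSEL, a homologue of dermatan sulfate epimerase, was 5.27-fold lower (4.34 to 6.45) from 1023 to 114 counts. ASAH2B, TIAM2, AGPAT4, PRSS16, FYB, CHFR, TMEM132B, ITGBL1, ADAM32 and ACPL2 completed the 15 lowest, between 4.11-fold and 7.34-fold lower.

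At the high end, GYG2, a glycogenin that primes glycogen synthesis, had 0 counts in the control and 86 in the knockdown library. That is at least 48.8-fold higher against the floor of 3 counts, and 38.8-fold or more by the exact interval. TBX2, a T-box transcription factor, had 1 count against 95, a ratio of 162 with a counting interval of 28.3 to 6454. ACPP, the prostatic acid phosphatase, was 15.7-fold higher (8.14 to 33.7), SCG2, a secretogranin, 11.1-fold higher (6.17 to 21.8) and SMAGP 10.6-fold higher (5.98 to 20.1). IFI6, an interferon-inducible gene, was 4.99-fold higher (3.52 to 7.20). GAB2, a docking protein of receptor tyrosine kinases, was 4.37-fold higher (3.40 to 5.66), and CSF2, the cytokine GM-CSF, 4.16-fold higher (3.07 to 5.70). DBP, EYA1, HES7, B3GNTL1, PLEKHG6 and PRX, together with IRF3, completed the 15 highest, between 4.31-fold and 6.19-fold higher. Most genes past 2-fold had few counts. Of 1716 genes whose higher library lay between 1 and 5 CPM, 712 (41.5%) differed at least 2-fold, against 295 of 5270 (5.60%) between 5 and 50 CPM and 12 of 4793 (0.25%) at 50 CPM or more. Counting error alone gave 28.4 such genes on average over 20 simulations, against 1019 observed. With a minimum of 5 CPM the comparison gave 161 higher and 146 lower genes.

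**Figure D1:**
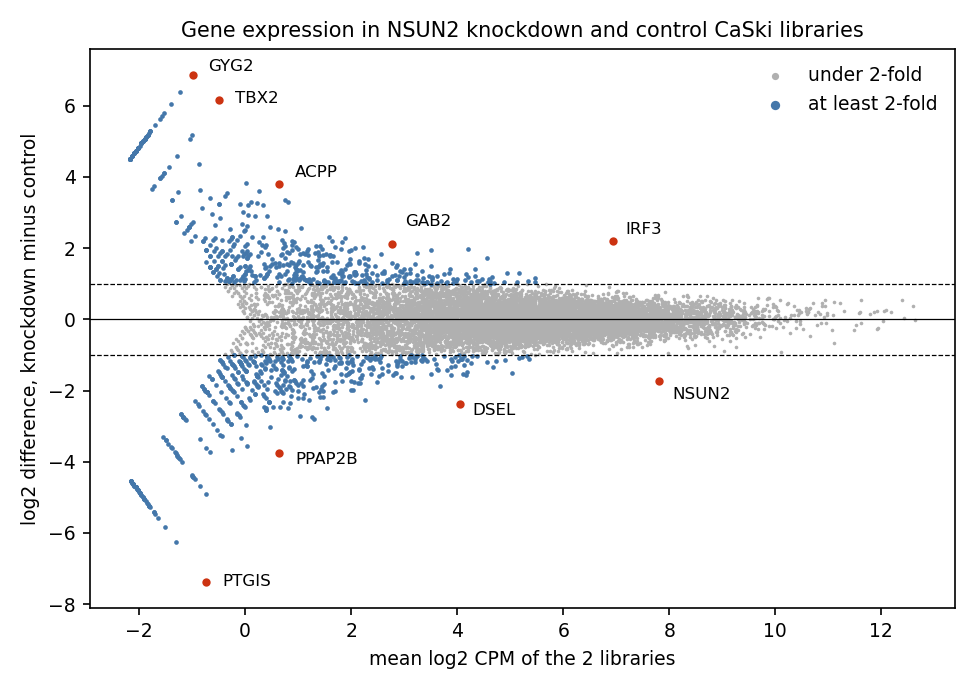
Log2 difference of knockdown minus control (vertical) against the mean log2 CPM of the 2 libraries (horizontal), 1 point per gene at 1 CPM or more. Blue points differ at least 2-fold, dashed lines mark that limit, and red points are named; NSUN2 (-1.73) and IRF3 (2.19) stand apart among abundant genes, while most other blue points lie at low expression.

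Of the 39 gene lists with at least 4 measured members, 9 had medians above the 97.5 percentile of random lists and 0 below the 2.5 percentile. Independent draws of genes would give 1.95 in both directions together. Members of a list may vary together and lists share members, so the number to be seen without a knockdown effect is not known. With a minimum of 5 CPM, 8 of the 36 lists that still had at least 4 members lay above and 3 below that range. Genes of the translation and energy machinery made up several of the 9. Among cytosolic ribosomal proteins and elongation factors 71 of 79 had a log2 difference above 0, and 1 was at least 2-fold higher. Their median of 0.30 lay above every random list. RPS29 (0.67), RPL28 (0.60) and RPL35 (0.55) were among those furthest from 0. All 5 measured mitochondrially encoded respiratory genes were above 0 but within 2-fold, with a median of 0.56 (percentile 99.94). Among them were MT-ND5 at 0.57, MT-ND2 at 0.56 and MT-CO3 at 0.54. The 6 mitochondrial genes in the table, MT-CO1 among them with 0 counts, took 0.519% of counts in the control and 0.745% in the knockdown library. Nuclear-encoded subunits of oxidative phosphorylation had a smaller median of 0.14 (percentile 98.82), with 30 of 46 above 0. NDUFB10 at 0.93 and NDUFA9 at -0.83 lay on opposite sides. Replication-dependent histones were above 0 in 25 of 27 cases, with a median of 0.35 above every random list. Only HIST1H3C passed 2-fold (2.35-fold higher, 2.05 to 2.70). Reads of histone genes can be shared between near-identical copies.

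Metabolic and stress lists formed the rest of the 9, apart from 2 described further on. Glycolysis had a median of 0.21 (percentile 98.96), with 15 of 20 genes above 0. SLC16A3, the lactate exporter MCT4, stood at 0.34 and ENO1 at 0.28, while PGK1 was at -0.31. Targets of NRF2, the regulator of antioxidant genes, had a median of 0.32 (percentile 99.85) and 15 of 18 were above 0. ABCC3, an efflux transporter, was 8.51-fold higher (4.11 to 19.8) from 9 counts, and OSGIN1 (0.83) and HMOX1, the haem oxygenase (0.77), stayed within 2-fold. Genes of the integrated stress response and of amino acid supply had a median of 0.22 (percentile 99.26) with 21 of 26 above 0. PHGDH, the first enzyme of serine synthesis, stood at 0.60, SESN2 at 0.74 and CHAC1 at 0.92, whereas CTH was 2.22-fold lower (1.49 to 3.39).

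Markers of other cell types were examined because the culture is a single epithelial line. Of 5 measured fibroblast markers 3 were at least 2-fold higher, with a median of 1.18 (percentile 99.87). MMP2, a gelatinase, was 2.26-fold higher (2.0 to 2.56) from 454 to 604 counts. COL1A1 and MFAP5 passed 2-fold with at most 27 counts, and FAP, a fibroblast protease, was at -0.59. With a minimum of 5 CPM fewer than 4 of these markers remained. COL1A1 and MMP2 also belong to the mesenchymal and the metalloproteinase lists. Of leukocyte markers only CSF1R was measured, 2.99-fold higher (2.01 to 4.50). The 3 measured endothelial markers were ROBO4 at 1.63, CDH5 at 0.94 and EGFL7 at 0.78. These 4 genes were chosen for naming after their values were seen.

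The proposed mRNA substrates of NSUN2 from the literature had a median of 0.201 (percentile 97.79), just past the upper random limit of 0.197. The mean of the list was 0.015. None of the 20 measured members reached 2-fold, and 12 were above 0. KRT13, with 26 counts in the control and 0 in the knockdown library, is on this list but stayed under 1 CPM and was not among the 20. CDKN2A, which encodes p16 in its main form, stood at 0.48, and CEP55 at -0.64, FABP5 at -0.68 and CDK1 at -0.60 lay on the other side. Non-coding RNA substrates were not measured in this table of protein-coding genes.

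In the main analysis the squamous and proliferation lists lay within the range of random lists. All 4 simple epithelial keratins were above 0, with a median of 0.32 (percentile 97.09), among them KRT8 and KRT18 at 0.45 each. The 7 basal and stress keratins had a median of 0.19 (percentile 83.5), with KRT6A at 0.36 and KRT15 at -0.48. KRT13 (ENSG00000171401), a suprabasal keratin of non-cornified epithelia, had 26 counts in the control and 0 in the knockdown library. That is at least 5.09-fold lower against the floor of 3 counts, and the exact interval put the ratio of knockdown to control at 0.26 or less. Its level stayed under 1 CPM in both. KRT80 stood at 0.78 and KRT4 was 3.65-fold higher (1.88 to 7.45) from 14 counts. Of 11 genes of the cornified envelope and squamous differentiation, S100A9 was 2.09-fold higher (1.83 to 2.40) and KLK6 2.63-fold higher (1.76 to 3.98), and FLG, filaggrin, was at 0.88. The G2/M list had 22 of 33 members below 0 and a median of -0.14 (percentile 2.63), with CDK1 at -0.60, TTK at -0.56 and NEK2 at -0.53, while AURKB was at 0.63. The G2/M list fell below the range with a minimum of 5 CPM (percentile 2.05) and with no minimum (2.32). Of 33 G1/S genes LIG1, a DNA ligase, was 8.09-fold higher (4.29 to 16.6) from 12 counts, the others lay within 2-fold.

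Signalling and inflammatory lists also stayed inside the random range in the main analysis, with a few members past 2-fold. Among 28 interferon-stimulated genes IFI6 and IRF7 (2.90-fold higher, 2.29 to 3.69) passed 2-fold, and the list median was -0.02 (percentile 45.1). Among 23 cytokine and NF-kB genes, PTGS2, the inducible cyclooxygenase, was 2.65-fold lower (2.17 to 3.26). CXCL3 was 14.3-fold higher (5.67 to 46.3) from 5 counts, and IL1RN was at least 13.6-fold higher from 0 to 24 counts. Of 22 p53 targets FAS, a death receptor, had 47 counts against 0, at least 9.20-fold lower, and RRM2B was lower as given above. DLL1, a Notch ligand, was 2.17-fold lower (1.81 to 2.60), DKK1, a WNT antagonist, was at -0.99, and WNT4 was at least 15.9-fold higher from 0 to 28 counts. MMP13 was 4.21-fold lower (2.29 to 8.46), MMP28 2.30-fold higher (1.45 to 3.70) and MUC16, the CA125 antigen, 3.32-fold lower (2.05 to 5.64). Of 23 genes of cholesterol biosynthesis 17 were below 0, with a median of -0.15 (percentile 5.04). HMGCS1 stood at -0.78 and STARD4 at -0.82, while PMVK was at 0.66 and TM7SF2, the only member past 2-fold, was 2.27-fold higher (1.59 to 3.26). SCD, the stearoyl-CoA desaturase of the fatty acid list, was at -0.88. Growth factor genes had 16 of 21 members below 0 and a median of -0.20 (percentile 3.26), with VEGFC at -0.69 and BMP4 at -0.79. AREG, the only member past 2-fold, was 3.03-fold higher (1.26 to 7.77) from 9 to 16 counts. This list fell below the range with a minimum of 5 CPM (percentile 1.41) and with library totals not scaled further (1.56).

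**Figure D2:**
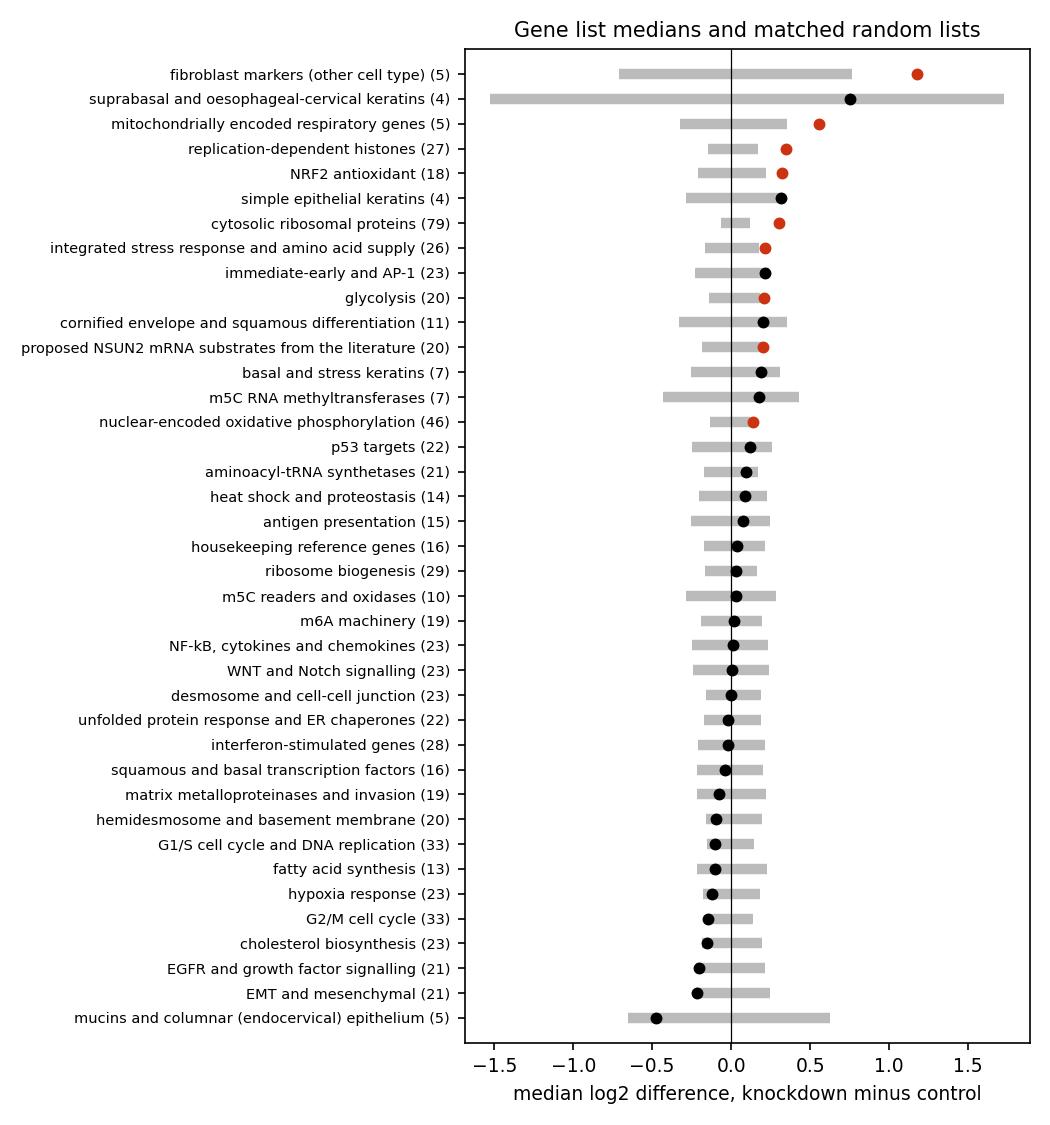
Median log2 difference of knockdown minus control for each of the 39 gene lists, with the number of measured members in parentheses. Grey bars span the central 95% of medians of random lists matched on expression, and red points are the 9 medians outside the 2.5 to 97.5 percentiles, which all lie above 0.

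The m5C table of the knockdown library was examined for which transcripts carried listed sites and at what level. With at least 20 covering reads, 5927 sites in 114 genes remained, and the lowest coverage among them was 30 reads. The median coverage was 50 reads (interquartile range 37 to 80). Mitochondrial transcripts held 2632 sites (44.4%, Wilson interval 43.1 to 45.7%) in 12 genes, led by MT-ND5 with 601 and MT-ND4 with 438. Among nuclear genes ACTB, encoding beta-actin, had 412 sites, the nuclear non-coding RNA MALAT1 243, ACTG1 135 and NCL, nucleolin, 118. The median methylation level was 98.2% (interquartile range 84.3 to 100%). It was 100% over mitochondrial and 88.4% over nuclear sites. A level of 95% or more was listed at 61.6% of sites (60.3 to 62.8%) and a level under 50% at 7.05% (6.43 to 7.73%). Genes differed in level. ACTB had a median of 70.2%, KRT17, a stress keratin, 56.1%, and FTH1, the ferritin heavy chain, 38.2%. The 39 sites that the deposited table assigns to the 5' UTR of WDR74 had a median of 22.8%. Up to 2099 reads covered these, against up to 320 at ACTB sites. In the knockdown RNA-seq library, however, WDR74 had 1177 counts and ACTB 112408. Whether the reads assigned to WDR74 came from its mRNA was not tested. SCG2, JAG1, PDIA4 and NR2F1 each had a median of 100%. The genes in this paragraph were chosen after their values were seen.

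Of the sites, 3571 (60.2%) were annotated to the coding sequence, 841 (14.2%) to the start codon class and 1025 (17.3%) to the stop codon class. The 3' UTR class held 375 (6.33%), of which 243 lay in MALAT1, a non-coding RNA. The 5' UTR class held 115 (1.94%), of which 39 were those assigned to WDR74. The start and stop codon classes are given as the deposited table names them, without a stated width. Sites lay close together: 97.7% (97.3 to 98.1%) had another listed site within 10 nt. Of 6728 other cytosines within 10 nt of a site, 5793 (86.1%, 85.3 to 86.9%) were listed as sites themselves. CNGGG, the context described for NSUN2, surrounded 54 sites (0.911%, 0.699 to 1.19%). CTCCA, the context described for NSUN6, surrounded 110 sites (1.86%, 1.54 to 2.23%). A site at any cytosine of CTCCA was counted, but only at the first base of CNGGG, so these shares were not counted alike. Of the unlisted cytosines in the same windows, 778 had all bases of the context within a window. CNGGG was found at 14 of these (1.80%, 1.07 to 3.0%). The coverage of unlisted cytosines was not at hand. Some may be unlisted because fewer than 30 reads covered them, so they are not known to be unmethylated. Without mitochondrial sites, a split chosen after seeing the data, the share at listed sites was 1.31%, inside that interval. The unlisted cytosines were not split in this way. The 134 sites with no listed site within 10 nt lay in 54 genes and had a median level of 90.0%. Many of these, such as the site of SCG2 at position 224463266, had no other cytosine within 10 nt, so no neighbour could have been listed. Others had unlisted cytosines beside them. CNGGG was found at 5 of the 134 (3.73%, 1.60 to 8.44%), in SCG2 at 2 sites and in SEC62, RPS24 and YBX1 at 1 each. These genes were named after their values were seen.

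**Figure D3:**
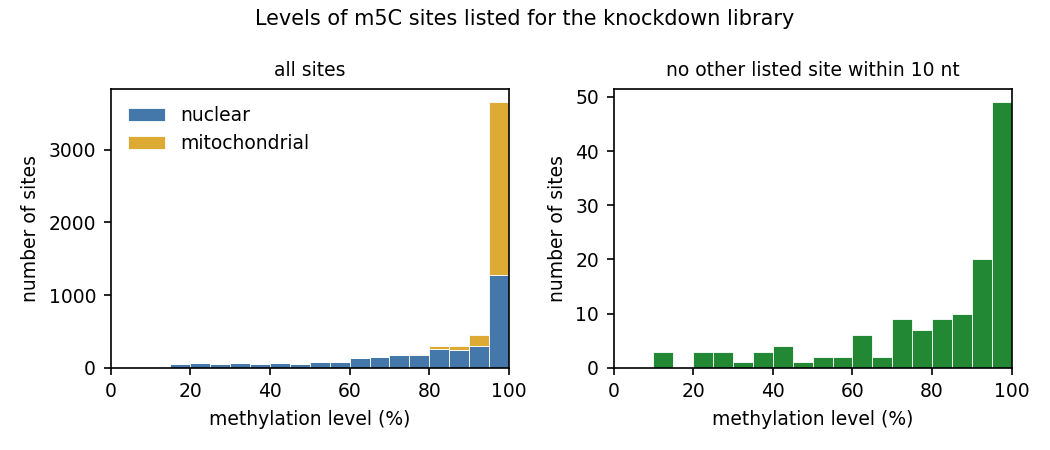
Number of listed m5C sites per methylation level in steps of 5%, for all 5927 sites on the left (nuclear and mitochondrial stacked) and on the right for the 134 sites with no other listed site within 10 nt. The highest step holds 2375 mitochondrial and 1275 nuclear sites on the left and 49 sites on the right.

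Sites were then described one by one under the naming rule. At 100 or more reads 518 of 1018 sites, in 12 genes, had a level of 100%. The 10 best covered of these all lay in the coding sequence of MT-ND4, a subunit of respiratory complex I, between positions 11007 and 11067 of the mitochondrial chromosome. The best covered, at position 11009, had C in 327 of 327 reads (100%, 98.8 to 100%). Of the proposed NSUN2 substrates, HDGF, ENO1, PKM and KRT13 carried listed sites. For KRT13, which may be on that list because of this series, this is not independent support. HDGF, a growth factor, had 11 sites in its coding sequence on chromosome 1, minus strand, from 156714029 to 156714109, with a median level of 83.3%. PKM, the glycolytic pyruvate kinase, had 17 sites on chromosome 15 at a median of 33.3%, in the 5' UTR, the coding sequence and near the stop codon. ENO1, an enolase, had 1 site on chromosome 1 at position 8934949 in the start codon class, with C in 7 of 31 reads (22.6%, 11.4 to 39.8%). KRT13 had 98 sites, all in the coding sequence on chromosome 17, minus strand, between 39659011 and 39661410 (hg19). They formed 5 blocks separated by more than 100 nt, covered by 30 to 71 reads, with levels from 96.7 to 100%. No read at these sites had a base other than C or T. The knockdown RNA-seq library had 0 counts of KRT13.

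**Figure D4:**
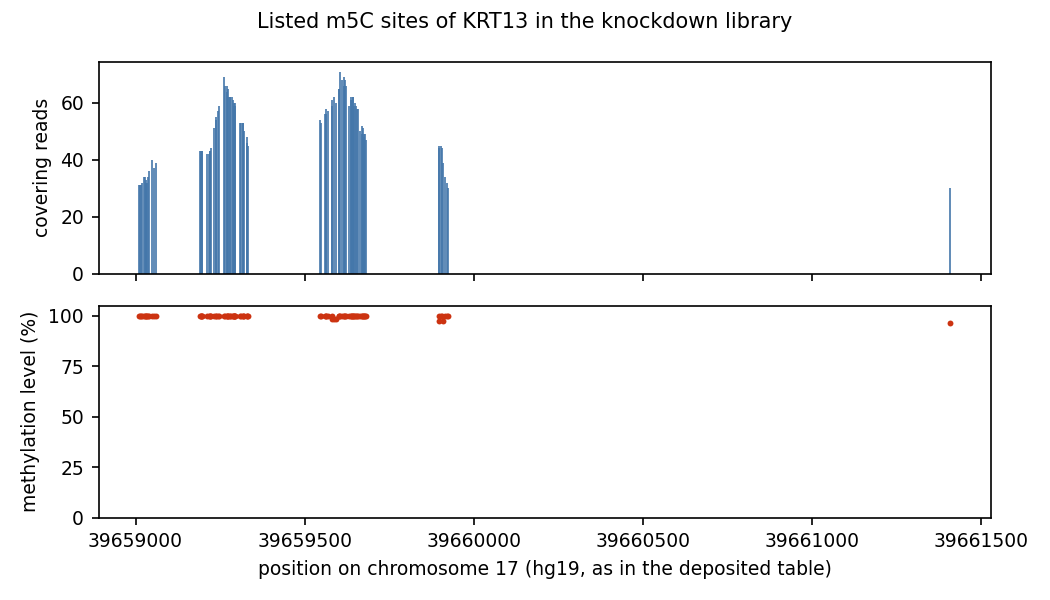
Covering reads (top) and methylation level in percent (bottom) of the 98 listed KRT13 sites by position on chromosome 17, 1 line or point per site of the knockdown m5C library. Coverage runs from 30 to 71 reads and every level is 96.7% or more.

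The tables were joined to ask whether genes with a listed site differed in expression between the libraries. Of the 114 genes 100 were measured, and 68 of them had a log2 difference above 0. SCG2 was the only one at least 2-fold higher. YWHAE, a 14-3-3 protein, was the only one at least 2-fold lower, with a log2 difference of -1.64. It had 215 counts in the control and 40 in the knockdown library, few beside its 15 sites at 30 or more reads. The read counter is not given, so whether these counts leave out reads of YWHAE is not known. The median log2 difference was 0.17 (percentile 99.96), while the central 95% of random lists matched on expression ran from -0.06 to 0.11. Sites were listed from the knockdown library only and at 30 or more reads, which favours genes higher in the knockdown, so part of this shift is built in. Against random lists matched on expression in the knockdown library alone, an alternative added after seeing the data, which ran from -0.01 to 0.14, the percentile was 99.71. Ribosomal protein and mitochondrial genes belong to lists that were themselves shifted upward. Without them, also chosen after seeing the data, the median of the 80 genes left was 0.13 (percentile 98.95). Its 95% interval over genes, -0.009 to 0.191, included 0, with 49 genes above and 31 below 0. Among all 100 genes, those such as TMSB10 (0.61), GNB2L1 (0.59) and RPL35 (0.55) lay above, and HMGB2 (-0.45), BCAT1 (-0.36) and VIM (-0.33) below 0. These and YWHAE were chosen after their values were seen. Among the 50 measured genes with a site that had no listed neighbour within 10 nt, the median was 0.07 and lay inside the random range (percentile 76.0). The difference of methylation level between knockdown and control was not analysed here, because values of the control m5C library were not used here.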

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

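All tests of explanations in this part, and the genes named with them, were chosen after the results were seen.

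The site table of the knockdown m5C library lists cytosines of the human papillomavirus type 16 reference, which no comparison used. There were 28 such sites, 16 assigned to E1^E4 and 12 to E7, with 1 to 4 covering reads each. They are given here because the 4 reads at the best covered of them exceed the 3 reads that a count of 0 allows, while every other listed site had at least 30 reads.

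Listed cytosines came in dense runs, in MT-ND5, MT-ND4, ACTB, MALAT1 and KRT13 among others, many of them at 100%. Methylation of single cytosines within a short target motif would leave most neighbouring cytosines unlisted, but 86.1% of them were listed. Mitochondrial transcripts alone do not account for the runs, since 79.4% of neighbouring cytosines were listed among nuclear sites. Stretches left unconverted by bisulfite as a whole in part of the molecules would give adjacent cytosines, covered by the same reads, nearly equal levels. At pooled levels of 20 to 80%, adjacent cytosines differed with 0.83 times the variance of independent counting error (0.67 to 0.999 over resampled genes). This argues against such stretches as the whole account of those sites. The ratio rose with distance, to 1.12 at 2 to 10 nt and 1.64 at 11 to 30 nt. At 31 to 100 nt it was 4.04 (1.86 to 5.26), so levels were more alike nearby than further apart. At the 61.6% of sites with a level of 95% or more, stretches unconverted in nearly all molecules cannot be told apart from methylated ones, and lower conversion or methylation of single cytosines across a region stays open as well, as does any part of NSUN2, because the control m5C and the mock libraries were not analysed here.

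KRT13 had 98 sites at 96.7% or more in a gene with 0 counts in the knockdown RNA-seq library. Few counts beside many sites were not particular to KRT13. MT-CO1 had 334 sites and 0 counts there, SCG2 103 sites at 96.8% or more and 85 counts, and NR2F1 31 sites and 84 counts. By contrast ACTB had 412 sites and 112408 counts, and LDHA 1 site and 88750 counts. The comparison with keratins bears on KRT13 only. Reads of KRT14, KRT17 or KRT19 would bring the levels of these keratins, but the lowest KRT13 level, 96.7%, lay above their highest, 93.5%, whereas reads of another type I keratin cannot be told apart, as 6 of them at 1 CPM or more had no listed site and so no level. Counting of the RNA-seq reads that leaves out every KRT13 read is excluded by the 26 counts of KRT13 in the control library. Counting that leaves out most of them cannot be told apart from KRT13 molecules present in the m5C library only, since MT-CYB, with 199 sites, had only 154 counts in the knockdown library and no table holds uncounted reads. No biological explanation was tested, since only 1 m5C library was analysed.

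IRF3 was 4.57-fold higher in the knockdown library, alone among genes at 100 CPM or more. A gain of its chromosome segment would move its neighbours alike, but the 10 nearest genes at 5 CPM or more had log2 differences of at most 0.60, with a median of 0.35. An interferon response across the list would move the interferon-stimulated genes up together. Their median log2 difference, however, had an upper 95% bound of 0.14, over the 28 genes of this library pair only. IFI6 and IRF7 alone passed 2-fold, and a response of a few genes cannot be judged from a median. Counts taken over from the adjacent gene BCL2L12 could not make up the difference, as BCL2L12 had 5 counts in the control library. Reads on both genes that were counted for neither, an interferon response of a few genes and an effect of the NSUN2 knockdown stay open. So does a difference between the cultures unrelated to the knockdown, all untested with 1 library each.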

How the results depend on the processing

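The log2 difference of NSUN2 stayed within its counting interval under every scaling, pseudocount and row choice tried, including DESeq2 size factors, unscaled library totals and the authors' deposited log2 values, which were chosen after seeing the data. Counts of genes past the threshold depended on the rule. A threshold of 1.5-fold gave 1313 higher and 1303 lower genes and 4-fold gave 175 and 173. No expression minimum gave 1251 and 1167, and a minimum of 5 CPM gave 161 and 146, since these rules admit more or fewer genes. Of the 9 lists that stood apart 8 did so in all 10 settings, and fibroblast markers lacked 4 members at 5 CPM. Settings that only rescale the libraries move list and random medians nearly alike, so their agreement adds little. No list lay below the random range in the main analysis, but at 5 CPM the mesenchymal (percentile 0.44), G2/M (2.05) and growth factor (1.41) lists did, as did G2/M with no minimum (2.32) and growth factors with library totals (1.56). Under another scaling 4 list medians near 0 changed sign. Coverage minimums of 10 and 30 reads removed no site. A minimum of 50 reads left 3003 sites with a median level of 99.2%, of which 98.2% had a site within 10 nt, 0.433% lay in CNGGG and 58.7% in the coding sequence. Without sites near another, 134 remained at a median of 90.0%, with 3.73% in CNGGG and 65.7% in the coding sequence, and the share with a neighbour has no value there. The median expression difference of site-bearing genes was then 0.070 and no longer stood apart. Matching on knockdown expression, chosen after seeing the data, kept it outside the random range for all genes with a site. Without mitochondrial sites, an alternative chosen after seeing the data, 3295 sites remained at 88.4%, with 96.0%, 1.31% and 56.7% in the same classes. The cause was not tested for any of these shifts in the site results. The difference of methylation level between knockdown and control was not run under any alternative. No replicate could be left out with 1 library per group, and no paired analysis was possible because each group has 1 library. Of 1281 recomputed differences of 183 named genes, 1269 stayed within their counting intervals. Rescaling moved differences little, that of NSUN2 lying between -1.76 and -1.73, and intervals at low counts are wide. Such agreement was therefore largely fixed in advance and adds little. Depth limits the size of differences at low counts, as 122 genes past 2-fold had 0 counts in 1 library and their folds are bounds.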

Other observations

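Several genes that belong to abundant families had almost no counts in either RNA-seq library. RPL13A, a ribosomal protein, had 14 counts in the control and 6 in the knockdown library, and MT-CO1 had 0 in both. MT-CYB had 140 and 154 counts, while MT-CO3 had 70325 and 60257. The counter that made the table is not given in the sources used here. These genes were chosen after their values were seen. Among genes past 2-fold, 122 had 0 counts and 63 had 1 to 3 counts in 1 library.

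All 10 genes nearest to IRF3 at 5 CPM or more were above 0, from 0.15 for SCAF1 to 0.60 for NOSIP, both chosen after their values were seen. The 9 lists that stood apart also all had medians above 0, and transcript length and GC content were not tested against either.

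The spread of log2 differences narrowed with the number of counts but stayed wider than counting error throughout. Among genes with 16 to 87 counts over both libraries it was 1.82, which is 4.45 times the spread from counting alone, and among genes with 9054 or more counts it was 0.30, which is 13.4 times.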
